A study of Homo sapiens with 10 samples.

How the data were processed

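Ribosome profiling and RNA sequencing were carried out on PLC/PRF/5 cells, a human hepatoma line, in wild-type (WT) cells and in cells with a knockout (KO) of TARBP1. The labels give 3 RNA libraries and 2 footprint libraries per genotype, 10 libraries in all, and every group was taken from the sample titles. Per the labels' protocols, cells were held in 100 µg/ml cycloheximide for 8 min before lysis. Lysates were digested with ribonuclease, and RNA from a gel slice between 17 and 34 nt went into the footprint libraries. The same protocol text is given for the RNA libraries, so how these were made is not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

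The authors deposited 1 table of read counts per gene for the RNA libraries and 1 for the footprint libraries, as whole numbers with no normalization. STAR 2.7.10a, StringTie 2.1.7 and the GRCh38 build are named for them per the submitters' processing notes. Which tool counted the reads, the annotation release, the use of strand, the treatment of reads with several matches and the handling of ribosomal RNA reads are not given in the sources used here. Each table had 60649 lines, of which 44 repeated a gene identifier and were removed, which left 60605 genes. Gene symbols were those the tables pair with Ensembl identifiers. Biotypes were taken from the authors' table of translational efficiency for 60388 genes, and gene positions and lengths were taken by symbol from a RefSeq table for GRCh38.p14.

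A further table deposited by the authors holds their own comparison of translational efficiency. Per the file headers it gives a ratio of footprints to RNA per genotype, the log2 fold change of KO over WT, a p-value with an adjusted p-value, and a dispersion score. The tool and the normalization behind that table are not given in the sources used here. It was used only for description.

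Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and the groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg (BH) adjustment. A gene was called at an adjusted p under 0.05. RNA abundance was fitted on the 6 RNA libraries alone and footprint abundance on the 4 footprint libraries alone. Translational efficiency, the ratio of footprints to RNA, was tested as the interaction of assay and genotype in 1 model over all 10 libraries. TMM factors for that model were taken within each assay, and genes had to pass the filter in both assays. Standard errors (SE) are the size of the log2 fold change divided by the square root of the F statistic. Levels per library are TMM-scaled CPM (counts scaled to a common library size), given as mean ± SD.

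Libraries held 17219504 to 34162245 counts, and 3 counts, the floor used where a group had no count, amounted to between 0.0854 and 0.19 CPM. Floors cover counting error only, because the reads carry no stated molecular identifiers. Pairs of replicates differed by far more than counting noise (chi-square per degree of freedom of 10.9 or more), so no library was counted as a duplicate.

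A set of 37 gene lists with 935 entries was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01. Lists with at least 5 tested members entered the test, with BH adjustment over the lists of a comparison. Counts of called members are given over all genes tested and adjusted over the list alone. Camera was repeated with an estimated correlation, and fry was run beside it. The named genes of a comparison were, in each direction, the 10 called genes with the largest fold change, a mean log2 CPM of at least 1, a symbol that is not a clone name, and every KO library on the same side of every WT library. TARBP1 and SLC1A5 were always given, with up to 4 members with the smallest p of each list described, and some of these members are not reported here. Genes outside that rule are said to have been chosen after their values were seen.

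The alternatives covered DESeq2 1.42.0 and its size factors, library totals without TMM, no filter and stricter filters, limma voom with and without quality weights, and the replicate number as a block. They also covered protein-coding genes alone, a requirement of a 2-fold change, and each library left out in turn. A trend with gene length was removed as a lowess offset per library in 1 further alternative. The tests were tried on simulated counts drawn from the real means, in which 100 genes were changed 2-fold and 100 genes 4-fold. The filter and the TMM factors were kept from the real counts and were not rerun. In RNA the test recovered 74% and 90% of these among 16070 genes. In footprints it recovered 2% and 36% among 16636 genes, and in translational efficiency 12% and 75% among 12783 genes. Unchanged genes called by mistake numbered 24 in RNA, 6 in footprints and 3 in translational efficiency. In RNA and footprints these were a larger share of the calls than the 0.05 aimed at. Every other gene was simulated without a change, whereas in the real RNA counts 31.5% of genes were called. Recovery under BH adjustment depends on the share of changed genes, so these percentages do not give the recovery in the real comparisons. A planned comparison with codon content needs coding sequences, which were not used here, and GC content was not analysed here.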

Results

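WT and TARBP1-KO cells of the hepatoma line PLC/PRF/5 were compared by RNA sequencing and by ribosome profiling, to find mRNAs whose translation depends on TARBP1, a tRNA ribose methyltransferase. Ribosome profiling counts the mRNA fragments that ribosomes shield from nuclease (footprints), so footprint counts follow both the amount of an mRNA and the number of ribosomes on it. Gene counts summed to 32302097, 32251236 and 34162245 in the WT RNA libraries and to 28521937, 33839538 and 30685870 in the KO RNA libraries. The footprint libraries held 17219504 and 29667417 counts in WT and 22634769 and 32293725 in KO. Mitochondrial ribosomal RNA took 27.9% and 20.6% of the WT footprint counts and 22.6% and 15.3% of the KO footprint counts, against 0.214% to 0.314% in RNA. Protein-coding genes held 62.5% to 75.2% of footprint counts and 97.4% to 97.7% of RNA counts. Replicates correlated at r = 0.981 to 0.986 across genes in RNA and at 0.93 and 0.94 in footprints.

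TARBP1 itself (ENSG00000059588; chromosome 1, 234391313 to 234479179 on GRCh38.p14) was lower in every KO library than in every WT library of both assays. Its RNA stood at 95.4, 90.5 and 76.3 CPM in WT and at 37.8, 40.5 and 47.7 CPM in KO, a fall to 48.1% (log2 fold change −1.06 ± 0.13 SE, n = 3 per genotype, edgeR quasi-likelihood BH-adjusted p = 0.00169). Its footprints stood at 90.4 and 118 CPM in WT and at 43.6 and 57.1 CPM in KO, 48.5% of WT (−1.05 ± 0.23, n = 2 per genotype), with an edgeR adjusted p of 0.0618. The ratio of footprints to RNA differed by 0.01 ± 0.25 (edgeR adjusted p = 0.99), and by −0.2 to 0.22 with each library left out in turn. Counts per gene do not show where in the gene the lesion lies or whether the remaining mRNA encodes protein. The footprint difference passed the threshold with no filter (adjusted p = 0.0408), with at least 50 counts on average in every group (0.0375), with DESeq2 (0.000377) and among genes with a count above 0 in every library (0.0208, chosen after seeing the data).

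SLC1A5 (ENSG00000105281; chromosome 19, 46774883 to 46788594), a plasma membrane transporter that imports glutamine, passed the threshold in none of the 3 comparisons. RNA was 288 ± 39.9 CPM in WT and 291 ± 36.0 CPM in KO (SD, n = 3), a log2 difference of 0.02 ± 0.13 (edgeR adjusted p = 0.923). Footprints were 266 ± 27.9 CPM in WT and 169 ± 1.32 CPM in KO (SD, n = 2), or 63.5% of WT (−0.66 ± 0.17, edgeR adjusted p = 0.0767). The footprint fall passed with DESeq2 (adjusted p = 0.000473) and with a count above 0 in every library (0.0459), and over the other alternatives without a fold requirement its adjusted p was 0.0519 to 0.323. Translational efficiency differed by −0.68 ± 0.21 with an edgeR adjusted p of 0.0515, just short of the threshold. The adjusted p of translational efficiency ranged from 0.018 to 0.132 over the alternatives without a fold requirement. It passed with a stricter filter (0.0403), with DESeq2 (0.0377) and with a count above 0 in every library (0.0439). It also passed with RNA replicates 1 and 2 only (0.018) and without RNA WT 3 (0.0304), RNA KO 3 (0.0333) or footprint WT 2 (0.0381). In the authors' deposited table the log2 change is −0.81 with an adjusted p of 4.61e-09. The RNA difference turned negative without RNA WT 1 (−0.04), WT 2 (−0.04), KO 1 (−0.05) or KO 2 (−0.02), and reached 0.23 (adjusted p = 0.0295) without both libraries numbered 3.

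**Figure D1:**
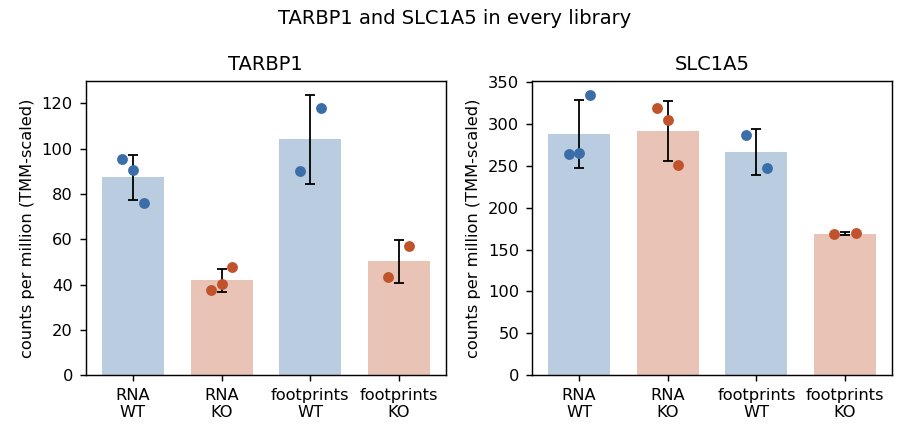
TMM-scaled CPM of TARBP1 (left) and SLC1A5 (right) in every library, with bars at the mean of each assay and genotype, error bars of 1 SD and 1 point per library (n = 3 for RNA and n = 2 for footprints). TARBP1 lies between 37.8 and 57.1 in all KO libraries and between 76.3 and 118 in all WT libraries, and SLC1A5 has means of 266 in WT and 169 in KO in footprints and of 288 and 291 in RNA, neither difference past the threshold.

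In RNA, the KO cells gained NTS, the precursor of the peptide neurotensin (ENSG00000133636; chromosome 12, 85874295 to 85882992), which rose from 11.8 to 416 CPM (log2 fold change 5.14 ± 0.18 SE, n = 3 per genotype). Among called genes with a gene name, a mean log2 CPM of at least 1 and no overlap between genotypes, the other rises of the 10 largest were COL11A1, a fibrillar collagen chain (5.27 ± 0.51, from 8, 0 and 5 counts in WT), SHISA7 (4.71), the secreted IGFBP7 (3.24), and the protease inhibitor SERPINE2 (3.07). The rest of these 10 were the kinase STK39 (2.64), the histone deacetylase HDAC9 (2.49), RASSF9 (2.47), the epoxygenase CYP2J2 (2.32) and ZNF804A (2.30). GPC3, a cell surface glypican used as a marker of hepatocellular carcinoma (ENSG00000147257; chromosome X, 133535745 to 133985594), fell to 8.29% of WT (−3.59 ± 0.13). The lipoprotein lipase activator APOC2 fell from 38.7 to 0.668 CPM (−5.88 ± 0.40), together with APOC4-APOC2 (−3.99), a readthrough gene that overlaps it and shares its reads. The other falls of the 10 largest by the same rule were TPTEP1 (−7.45 ± 0.80, with 0, 2 and 0 counts in KO), MFSD2B (−6.26), the neurofilament gene NEFH (−4.63) and the annexin ANXA6 (−4.30). They also held the adenosine receptor ADORA2A (−3.91), the metalloproteinase inhibitor TIMP3 (−3.64) and XAGE1A (−3.80), a cancer-testis antigen with near-identical copies whose counts are uncertain. ADORA2A lost its call with limma voom (adjusted p = 0.0763).

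Of 16070 genes tested, 5069 were called by edgeR's quasi-likelihood test at a BH-adjusted p under 0.05, 2716 higher and 2353 lower in KO. Changes of at least 2-fold made up 471 of the rises and 418 of the falls. The count fell to 3185 with no filter, to 2386 without WT 2, to 2564 without WT 3, to 3040 without KO 2 and to 2999 without KO 3.

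Genes that hepatocytes use for secreted proteins and metabolism fell as a group in KO RNA: 12 of 26 tested members fell and 2 rose, with the same counts adjusted over the list alone. CPS1, which starts the urea cycle (ENSG00000021826; chromosome 2, 210477685 to 210679107), fell from 888 ± 11.2 to 212 ± 12.1 CPM (SD, n = 3; log2 fold change −2.06). The fibrinogen chain FGB (−3.59), the plasma protein AHSG (−1.79) and the gluconeogenic enzyme PCK1 (−3.55) fell with it. The list passed camera at an adjusted p of 1.9e-13, and at an adjusted p of 0.0433 with an estimated correlation.

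Glycolytic genes also fell in RNA, 14 of 19 with none rising, and again 14 adjusted over the list alone. HK2, the hexokinase of many tumours (ENSG00000159399; chromosome 2, 74834127 to 74893359), fell by 3.20 on the log2 scale, the aldolase ALDOA by 0.83, the glucose transporter SLC2A1 by 0.59 and the phosphofructokinase PFKM by 0.76. Camera gave an adjusted p of 5.13e-06 for glycolysis, and an adjusted p of 0.613 with an estimated correlation. Of 17 interferon-stimulated genes 8 fell over all genes and 9 with 1 rise adjusted over the list alone, among them the antiviral OAS3 (−1.44), IFI6 (−1.56) and OAS1 (−1.07). Their camera adjusted p was 0.00126, and the adjusted p was 0.255 with an estimated correlation. Mitochondrially encoded transcripts rose, 11 of 13 both over all genes and adjusted over the list alone, including the complex I genes MT-ND4 (0.60) and MT-ND2 (0.45). Their camera adjusted p was also 0.00126, with an adjusted p of 0.701 with an estimated correlation.

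Smaller RNA shifts were seen in 3 further lists. Among cytosolic ribosomal protein genes 25 of 79 fell and 3 rose, with the same counts adjusted over the list alone (RPL10 −0.81, RPL17 0.76; camera adjusted p = 0.0176, and adjusted p = 0.715 with an estimated correlation). Many ribosomal protein genes have processed pseudogenes, so their counts are uncertain. Nuclear genes of oxidative phosphorylation had 13 falls and 2 rises of 37, or 15 and 2 adjusted over the list alone (NDUFA2 −0.62, COX5B −0.55, ATP5F1A 0.37; camera adjusted p = 0.0205, and adjusted p = 0.701 with an estimated correlation). DNA replication genes of S phase had 13 falls and 2 rises of 25, or 13 and 3 adjusted over the list alone. The helicase subunit MCM7 fell by 0.77 and the cyclin CCNE1 by 0.61 (camera adjusted p = 0.0316, and adjusted p = 0.439 with an estimated correlation). The S phase call was lost without RNA WT 2 (adjusted p = 0.0609), KO 1 (0.0733) or KO 2 (0.0536).

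Genes of glutamine transport and metabolism did not move as a group in RNA: 5 of 30 rose and 9 fell, or 7 and 10 adjusted over the list alone (camera adjusted p = 0.728). The asparagine synthetase ASNS rose by 0.51, while the transaminase GPT fell by 1.78 and the purine enzyme PFAS by 0.47. G2/M genes had 13 rises and 6 falls of 25, the same adjusted over the list alone, without passing camera (adjusted p = 0.087). Of markers of other cell types, the pericyte and fibroblast receptor PDGFRB fell (−1.57, 1 of 2 fibroblast markers tested) and LYZ rose (0.83, 1 of 3 leukocyte markers). The biliary markers SOX4 (0.97) and SOX9 (0.57) rose among 5 tested (camera adjusted p = 0.717), and none of 3 endothelial markers passed.

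RNA differences followed gene length. Across 14135 genes with a length, the log2 fold change had a Spearman rho of 0.309 with genomic length, with longer genes higher in KO, although genes are not independent replicates. With the trend removed per library, an alternative chosen after seeing the data, 4734 genes were called, and 3784 (78.5%) of the 4820 called before kept their call. The falls of the hepatocyte list (adjusted p = 2.1e-10), glycolysis (2.88e-06) and interferon-stimulated genes (0.00479) kept their calls by camera. Ribosomal protein genes (adjusted p = 0.818), oxidative phosphorylation (0.436) and S phase (0.0793) lost theirs, G2/M genes passed with a rise (0.0489), and the mitochondrially encoded list had no lengths and was not tested. Relative to all genes, the list median went from −0.17 (quartiles −0.38 and 0.03) to 0.02 (−0.16 and 0.24) for ribosomal proteins and from −0.28 (−0.45 and −0.01) to −0.09 (−0.32 and 0.12) for oxidative phosphorylation. For S phase it went from −0.26 (−0.41 and 0.09) to −0.17 (−0.43 and 0.07). With the trend removed, 11 of 25 S phase members were called lower and 2 higher. Among oxidative phosphorylation genes with a length, 11 of 36 were called lower and 3 higher. Of 79 ribosomal protein genes, 7 were called lower and 14 higher. In each of these lists the median moved by less than the spread of its members, so the lost calls do not assign these falls to gene length.

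**Figure D2:**
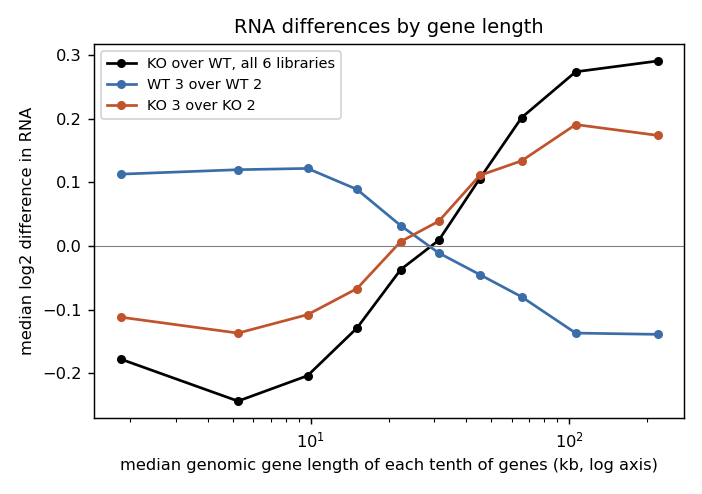
Median log2 difference in RNA (vertical axis) for 10 groups of 14135 genes ordered by genomic length in kb (horizontal log axis), with black for KO over WT in all 6 libraries, blue for WT 3 over WT 2 and orange for KO 3 over KO 2. The medians run from −0.178 in the shortest group to 0.291 in the longest for KO over WT, from 0.113 to −0.139 for the WT pair and from −0.112 to 0.174 for the KO pair.

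In footprints, the genes with the largest changes by the rule used for RNA were present in all libraries of 1 genotype and absent from the other. The fold bounds given for them cover counting error only and are not bounds on an effect of the knockout. Between the 2 libraries of 1 genotype, 51 to 178 genes were also at 0 in 1 library and at 50 or more in the other. Another 33 genes were at 0 in both libraries numbered 1 and at 50 or more in both numbered 2. CCDC167 had 945 and 1439 footprint counts in WT and none in KO, at least 509-fold lower against a floor of 3 counts per library, while its RNA stayed at 83.3% of WT. RFXANK, which activates MHC class II genes, was at least 297-fold lower in KO, TMEM98 at least 117-fold, the adaptor subunit AP1M2 at least 80.4-fold, SPINDOC at least 67.7-fold, the collagen COL5A3 at least 62.1-fold and GMIP at least 60.7-fold. The small RNA SCARNA2 was lower by at least 119-fold, MROH7-TTC4 at least 200-fold and RAB4B-EGLN2 at least 110-fold. Present in KO alone were the annexin ANXA1 at a level at least 132-fold higher, the disulfide isomerase AGR2 at least 67.7-fold and the convertase PCSK5 at least 62.4-fold. NCAM2 was higher by at least 49.0-fold, IMMP2L by at least 41.4-fold, and the vitamin D hydroxylase CYP24A1 and the receptor ERBB4 each by at least 38.8-fold. DHRS12 was higher by at least 38.7-fold, the pseudogene MRPL32P2 at least 50.8-fold and ISY1-RAB43 at least 225-fold. Readthrough genes share reads with the genes they overlap. ISY1 went from 339 and 650 counts in WT to 7 and 13 in KO while ISY1-RAB43 went from 0 to 746 and 1188, and TTC4 went from 4 and 0 to 690 and 973 while MROH7-TTC4 went from 307 and 685 to 0.

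Among genes with counts in every footprint library, a set chosen after seeing the data, SERPINE2 (log2 fold change 3.68 ± 0.34 SE, n = 2 per genotype), the matrix protein LUM (3.82), the growth cone protein BASP1 (3.49), the acetyltransferase NAT2 (2.79) and the guidance cue SEMA3A (2.74) rose. The receptor IL17RC (−3.68), SPTSSB (−3.49), CLEC2D (−3.31) and the tetraspanin CD81 (−3.22) fell. BASP1 has a pseudogene, so its counts are uncertain. Of 16636 genes tested, 415 were called by edgeR's quasi-likelihood test with BH adjustment, 202 higher and 213 lower in KO (48.7% higher), all at an adjusted p between 0.0476 and 0.05. With library totals in place of TMM, which shifted the median of all genes to 0.145, 216 were higher and 121 lower (64.1% higher). Of the 415, 88 had no footprint count in 1 genotype, 51 in WT and 37 in KO, and at an unadjusted p under 0.05 there were 5585 genes. By edgeR the count was 0 without footprint WT 1 or WT 2, 87 without KO 1 and 292 without KO 2. It was 1719 with no filter, 1694 with a stricter filter, 3585 with DESeq2, 633 with limma voom, 1285 among protein-coding genes and 3064 among genes with a count above 0 in every library. With the replicate number as a block it was 0.

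Of 31 replication-dependent histone genes, which supply histones in S phase, 3 fell in footprints over all genes and 15 adjusted over the list alone, including H4C5 (−1.69), H4C8 (−1.21) and H2BC12 (−1.65). The list passed camera (adjusted p = 5.04e-11), but not with an estimated correlation (0.887) or with fry (0.235). These genes are near-identical copies of each other, so their counts are uncertain. Citric acid cycle genes had 1 rise of 25 and 5 adjusted over the list alone, with the cytosolic malate dehydrogenase MDH1 at 1.31. With library totals the calls of H4C8 (adjusted p = 0.0554), H2BC12 (0.0513) and MDH1 (0.0539) were lost. Oxidative stress targets of NRF2 had 2 rises of 18, and 7 with 1 fall adjusted over the list alone, with NQO1 at 1.71 and AKR1C3, which has close paralogs, at 1.81. Aminoacyl-tRNA synthetases (8 higher and 1 lower of 23 adjusted over the list alone), mitochondrial ribosomal proteins (4 and 1 of 37), selenoproteins (1 and 8 of 18) and genes of the unfolded protein response (1 and 5 of 20) had no member called over all genes. Camera gave an adjusted p of 0.0302 each for the citric acid cycle, NRF2 targets, synthetases and selenoproteins, 0.0478 for mitochondrial ribosomal proteins and 0.0494 for the unfolded protein response. The adjusted p was 0.887 with an estimated correlation for each, and 0.158 with fry. Histones kept their camera call without any 1 library, and every other list lost its call without WT 2 (adjusted p of 0.0564 to 0.152). Mitochondrial ribosomal proteins also lost it without WT 1 (0.0536), KO 1 (0.0903) or KO 2 (0.0501), and the unfolded protein response without KO 1 (0.141) or KO 2 (0.0982). The citric acid cycle and NRF2 targets lost it without KO 1 (0.0846 each), and synthetases (0.0514) and selenoproteins (0.214) without KO 2.

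**Figure D3:**
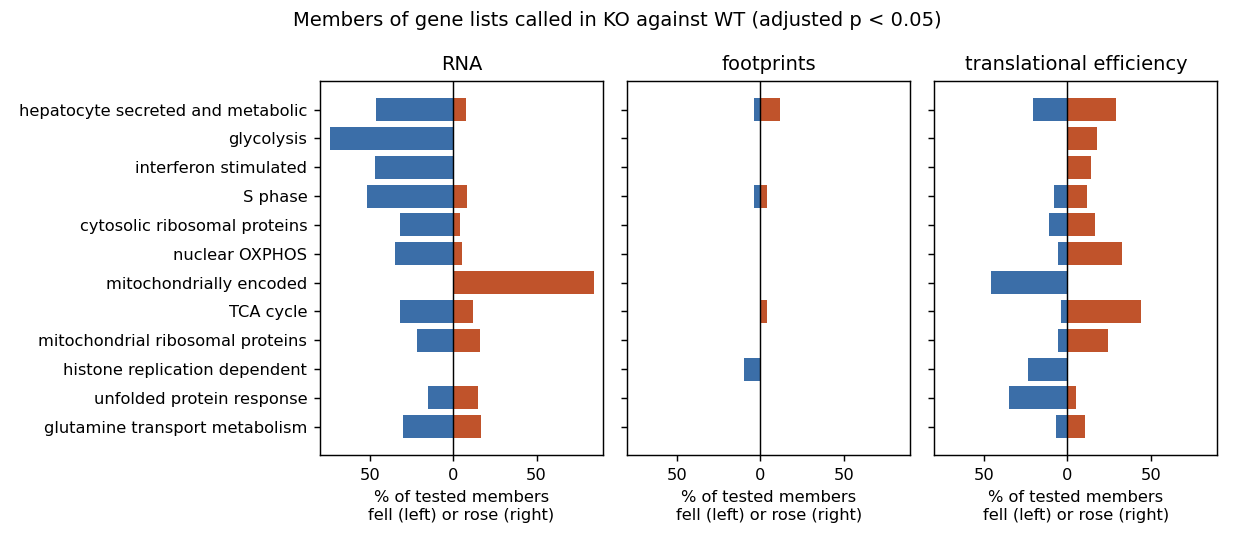
Percent of the tested members of 12 gene lists called higher (orange, right) or lower (blue, left) in KO at an edgeR adjusted p under 0.05 in RNA, footprints and translational efficiency. Glycolysis falls in RNA (14 of 19 members), 11 of 13 mitochondrially encoded genes rise in RNA and 6 of 13 fall in translational efficiency, and 11 of 25 citric acid cycle genes rise in translational efficiency.

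Translational efficiency, the footprint change beyond the RNA change, rose in KO for part of the genes in 3 lists of nuclear genes linked to mitochondria. These lists passed camera and fry but not camera with an estimated correlation. Of 37 oxidative phosphorylation genes 12 rose and 2 fell, or 14 and 2 adjusted over the list alone, with the ATP synthase subunit ATP5F1B at 0.90 and the complex III subunit UQCRB at 1.08. Of 25 citric acid cycle genes 11 rose and 1 fell, or 13 and 1 adjusted over the list alone. The rises included the dehydrogenases IDH2 at 1.57, IDH3B at 1.08 and SDHB at 1.02, and MDH1, the cytosolic malate dehydrogenase, at 1.14. Of 37 mitochondrial ribosomal proteins 9 rose and 2 fell, or 13 and 2 adjusted over the list alone (MRPS7 0.82, MRPS15 0.76, MRPL32 −0.91). The mitochondrially encoded genes went the other way, with 6 of 13 falling and 9 adjusted over the list alone, among them the cytochrome oxidase subunits MT-CO1 (−0.84) and MT-CO3 (−0.86). The median of all 12783 genes was −0.197, or −0.0711 with library totals, and relative to it the list medians were 0.64, 0.78, 0.54 and −0.58 in that order. Camera gave adjusted p values of 1.79e-05, 1.79e-05, 0.000134 and 0.00454, and with an estimated correlation the adjusted p was 0.276, 0.123, 0.0698 and 0.398. In footprints alone, 0 of 13 mitochondrially encoded genes (camera adjusted p = 0.144) and 0 of 37 oxidative phosphorylation genes (0.0765) were called. RNA changes in the opposite direction therefore carry part of these 2 ratios. Whether the cycloheximide step holds mitochondrial ribosomes was not tested here. The call of the mitochondrially encoded list was lost without footprint KO 2 (adjusted p = 0.0584), and MRPL32 lost its call with the length trend removed (−0.71, 0.0807).

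The hepatocyte list that fell in RNA had 7 rises and 5 falls of 24 in translational efficiency, the same adjusted over the list alone, with the largest in CPS1 (3.73 ± 0.17 SE) and a rise in transferrin TF (1.68), and a fall in the glucose-6-phosphatase G6PC1 (−1.90). Glycolysis had 3 rises of 17, or 4 with 1 fall adjusted over the list alone, led by HK2 (3.91) and PFKP (1.23). Proteasome genes had 2 rises and 1 fall of 30, the same adjusted over the list alone (PSMB5 1.22, PSMB2 1.08), and NRF2 targets 4 rises and 1 fall of 18, or 5 and 1 adjusted over the list alone (NQO1 1.72). Camera gave adjusted p values of 0.000458, 0.012, 0.0349 and 0.0451 for these 4 lists, and with an estimated correlation the adjusted p was 0.0698, 0.464, 0.276 and 0.398. In footprints alone the hepatocyte list had 3 rises and 1 fall of 26 (camera adjusted p = 0.614), and glycolysis had 0 of 17 called (0.565). In translational efficiency histones had 4 falls of 17, the same adjusted over the list alone (H1-2 −2.12, H2BC12 −1.59). Only 17 of 31 histone genes passed the filter in RNA, and the authors' deposited table gives WT ratios of footprints to RNA of 1050 in H4C5 and 3.09 in H2BC12. How the RNA libraries captured histone mRNAs is not given in the sources used here, so these ratios are uncertain. Chaperones and enzymes of the unfolded protein response had 7 falls and 1 rise of 20, or 9 and 1 adjusted over the list alone (CANX −1.37, SYVN1 −1.88, PDIA6 −0.91). Relative to the median of all genes, the list medians were 0.65, 0.40, 0.39, 0.28, −0.78 and −0.38 for these 6 lists in order. The camera adjusted p values of the last pair were 0.0199 and 0.0349, and with an estimated correlation the adjusted p was 0.464 and 0.248. Without footprint WT 1 the calls of histones (0.077) and the proteasome (0.0796) were lost. Without WT 2 those of glycolysis (0.15), the proteasome (0.0534), the unfolded protein response (0.0748) and NRF2 targets (0.15) were lost. Without KO 1 those of the proteasome (0.122), the unfolded protein response (0.122) and NRF2 targets (0.136) were lost, and without KO 2 those of histones (0.0993) and the unfolded protein response (0.0732). The NRF2 call was also lost without RNA WT 2 (0.054), WT 3 (0.0734) or KO 3 (0.108), and with the replicate number as a block (0.0566). The unfolded protein response call was also lost with the length trend removed (0.0627). The median of that list relative to all genes was −0.38 (quartiles −0.73 and 0.08) before and −0.34 (−0.77 and 0.14) after, so the lost call does not assign its fall to gene length.

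Genes of glutamine transport and metabolism showed no shared change in translational efficiency: 3 of 28 rose and 2 fell, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.635). The proline synthesis enzyme ALDH18A1 rose by 0.83 and the CTP synthase CTPS1 by 0.58, and glutamate dehydrogenase GLUD1 (−0.70) and glutamate decarboxylase GAD1 (−0.83) fell. The call of CTPS1 was lost without RNA WT 2 (adjusted p = 0.0694), RNA KO 2 (0.0621), footprint WT 1 (0.0595) or footprint KO 2 (0.0641). That of GLUD1 was lost with library totals (0.0638) and without RNA WT 2 (0.0551) or footprint KO 1 (0.0536). That of GAD1 was lost with library totals (0.0528) and without each library except RNA WT 3 and footprint WT 2 (0.053 to 0.0811). Genes that encode long glutamine tracts had 1 rise and 4 falls of 28, the same adjusted over the list alone, with TBP at −1.32, MED12 at −1.05 and MED15 at 1.54 (camera adjusted p = 0.585, fry 0.00696). The list median of −0.227 lay near the −0.197 of all genes, with which fry does not compare a list.

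Of 12783 genes tested for translational efficiency, edgeR's quasi-likelihood test with BH adjustment called 2291, of which 778 rose and 1513 fell (34% higher). Of these, 97 rises and 155 falls were also called in footprints in that direction, and 328 and 437 were called in RNA in the opposite direction. The split was 1008 to 1043 (49.1% higher) with library totals and 1235 to 1261 (49.5% higher) with the length trend removed. The genes with the largest changes by that rule lacked footprints in 1 genotype, as in the footprint comparison: ANXA1, AGR2, IMMP2L, CYP24A1 and DHRS12 rose, and CCDC167, RFXANK, TMEM98, COL5A3, GMIP, SPINDOC and AP1M2 fell. The troponin TNNT1 (footprints at least 20.8-fold higher), SSBP2 (at least 18.2-fold), DPF1 (at least 13.3-fold), the nuclear body protein SP100 (at least 27.7-fold) and FBXL21P (at least 57.6-fold) also rose. The topoisomerase TOP3B (at least 87.3-fold lower), PPT2-EGFL8 (at least 183-fold) and HGH1 (at least 46.1-fold) also fell. These fold bounds again cover counting error only. FBXL21P was lost when any single library except footprint KO 2 was left out (adjusted p of 0.0531 to 0.0967). Among genes with counts in every library, chosen after seeing the data, APOC2 (6.64), the ephrin receptor EPHA5 (4.93), BASP1 (4.82), XAGE1A (4.36), HK2 (3.91) and the phosphatase DUSP4 (3.89) rose. In the same set IGFBP7 (−5.72), CD81 (−4.21), the fucosyltransferase FUT4 (−3.35) and the Wnt receptor FZD5 (−3.34) fell. The count was 1511 without RNA WT 1, 1221 without RNA WT 2, 1288 without RNA KO 2, 1346 with limma voom and quality weights, and 1436 with a change of at least 2-fold.

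In the authors' deposited table, 2671 of 14864 genes with a p-value have an adjusted p under 0.05, 1273 higher and 1398 lower in KO. Over 12752 genes in both, its log2 changes and those of the edgeR interaction had a Spearman rho of 0.952 across genes, with the authors' values higher by a median of 0.107. In all 1815 genes called in both the sign was the same, 658 were called in the authors' deposited table alone and 467 by edgeR alone.

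RNA and footprint changes followed each other loosely. Over the 12783 genes tested in both, the log2 fold changes had a Spearman rho of 0.414 and a Pearson r of 0.257 across genes, which are not independent replicates, and 66.9% had the same sign. Of 147 genes called in both assays, 53 rose in both (29.3 for independent lists), 64 fell in both (27.9), 22 fell in RNA and rose in footprints (23.4), and 8 rose in RNA and fell in footprints (35). SERPINE2 rose in both (3.07 and 3.68), and NTS rose in both (5.14 and 2.09), with footprints already at 745 CPM in WT, where its RNA was 11.8 CPM. CPS1 went in opposite directions in the assays, with footprints rising from 261 ± 37.2 to 831 ± 50.5 CPM (SD, n = 2) as its RNA fell. Among genes tested in both assays, 9 were called in RNA with a rise of at least 8-fold, and 3 of these had a footprint change under 2-fold or in the other direction. Of the 26 called in RNA with a fall of at least 8-fold and tested in both, 17 had such a footprint change, among them HK2 (−3.20 in RNA, 0.71 in footprints), GPC3 (−3.59 and −0.16), APOC2 (−5.88 and 0.77), FGB (−3.59 and −0.89) and PCK1 (−3.55 and −0.76).

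**Figure D4:**
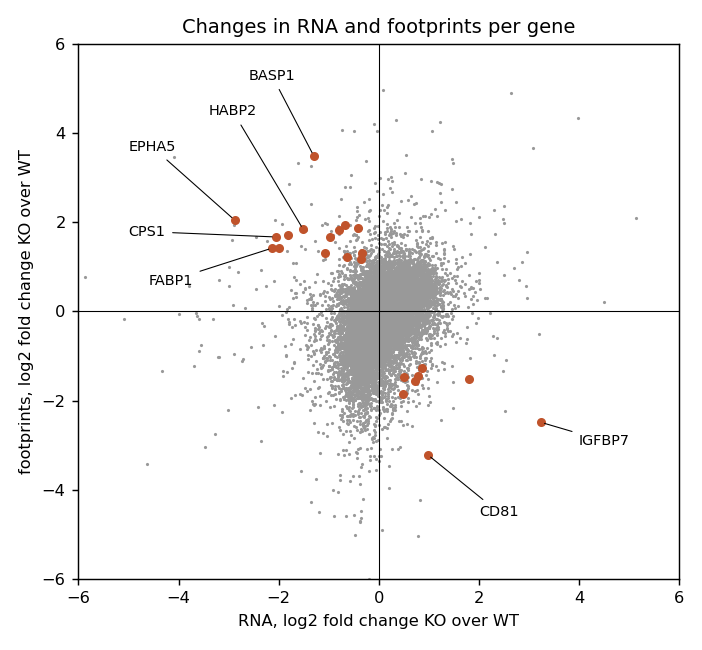
Log2 fold change of KO over WT in RNA (horizontal axis) and in footprints (vertical axis), with 1 grey point per gene for 12658 of 12783 genes (125 lie beyond the axes) and orange points for the 23 genes called in opposite directions with counts above 0 in every library. CPS1, HABP2, BASP1, FABP1 and EPHA5 lie at upper left, lower in RNA and higher in footprints, and IGFBP7 and CD81 at lower right.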

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

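The tests on exchanged genotype labels and on footprint counts alone were chosen only after the result was seen. In 30 genes RNA and footprints were called in opposite directions between KO and WT. Of these, 22 fell in RNA and 8 rose, against 23.4 and 35 for independent lists. Because the genes were picked by these calls, an interaction on the same libraries was nearly certain to pass. Its p-values below are therefore no further support. By edgeR's quasi-likelihood test with BH adjustment, the log2 change in footprints exceeded that in RNA by 3.73 ± 0.17 SE in CPS1 (adjusted p = 5.99e-06) and by 3.35 ± 0.17 in HABP2 (9.19e-06). The excess was 2.63 ± 0.34 in the kynureninase KYNU (0.00156), 2.62 ± 0.20 in the guanylate-binding protein GBP2 (0.000105) and 2.62 ± 0.31 in TENT5A (0.00109). In TENT5A the RNA call was lost without RNA WT 2 (−0.67, adjusted p = 0.0525) and with the length trend removed (−0.48, 0.0547). The footprint calls of CPS1, KYNU and GBP2 were lost without any 1 footprint library, with CPS1 between 1.53 and 1.83 in these fits. That of HABP2 was lost without footprint WT 1 (adjusted p = 0.152), WT 2 (0.0596) or KO 1 (0.0721), and that of TENT5A without WT 1 (0.167), WT 2 (0.0757) or KO 1 (0.125).

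An exchange of genotype labels in 1 assay is excluded for these libraries, because TARBP1 in KO stood at no more than 48.5% of WT in either assay. Of the 30 genes, 21 had at least 50 footprint counts on average in both genotypes, so low footprint counts by that mark do not cover these 21. That test cannot exclude low footprint counts for the set, because genes called in these footprint libraries were likely to be well counted. Low footprint counts stay open for the other 9. Low counts in either assay also stay open, since 14 of the 30 reached that level in both genotypes of both assays. Different cultures or clones behind the RNA and footprint libraries also stay open: of 638 genes called in RNA with at least a 2-fold change, 71.3% had a footprint change of the same sign. A change in translation without TARBP1 may account for part of the pattern, as a hypothesis that these libraries cannot separate from the other open explanations.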

How the results depend on the processing

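The alternatives with a length trend removed, a count above 0 in every library, both RNA libraries numbered 3 left out, and TMM over the genes tested for translational efficiency were chosen after seeing the data. All others, the gene lists and the rule for named genes were fixed before the data were examined. The 5069 genes called in RNA became 3185 with no filter, 889 with at least a 2-fold change and 2386 to 4577 with each library left out. The 7 RNA lists became 1 with an estimated correlation, 14 with fry (6 of the 7 among them), 4 of 33 tested with the length trend removed (3 of the 7, without the mitochondrially encoded list, which had no lengths) and 6 to 9 with each library left out. The 415 genes called in footprints became 1719 with no filter, 1694 with at least 50 counts on average, 3585 with DESeq2, 633 with limma voom, 1285 among protein-coding genes and 3064 with a count above 0 in every library. They became 0 to 292 by edgeR with each library left out, against 5585 at an unadjusted p under 0.05 with all libraries. In those fits the lone library is assumed to vary like the other group. The 7 footprint lists became 0 with an estimated correlation, 1 with fry, amino acid transporters, which was none of the 7, and 1 to 7 with each library left out, of which 1 to 6 were among the 7. The 2291 genes called in translational efficiency became 1436 with at least a 2-fold change, 1346 with voom quality weights and 1221 to 3173 with each library left out, and its 10 lists became 0 with an estimated correlation and 6 to 11 with each library left out. The 2-fold counts are subsets by construction, and otherwise the cause was not tested.

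In RNA, deviations of libraries with the same replicate number correlated at −0.17, −0.02 and −0.23. No effect of the number that moves both genotypes the same way was thus seen in RNA. An effect of the number with opposite directions in WT and KO stays open. In footprints, deviations of libraries with the same number correlated at 0.1. The second principal component (24.1%) there set the libraries numbered 1 (33.9 and 57.7) apart from those numbered 2 (−45.2 and −46.3). An effect shared by the number therefore stays open in footprints. With the number as a replicate block, 695 genes were called in RNA, 0 in footprints by edgeR and 1056 in translational efficiency. Signs turned for values that were not called: SLC1A5 in RNA ran from −0.05 to 0.14 with each library left out. TARBP1 in translational efficiency was −0.03 with at least 50 counts on average, 0 with a count above 0 in every library and −0.2 to 0.22 with each library left out. TIMP3 in footprints was 0.05 with library totals and −0.38 to 0.14 with each library left out. Of the values of single named genes under alternatives, 3493 kept direction and side of the threshold, 299 lost the threshold, 24 passed it and 15 turned sign. The comparison with codon content and its 4 alternatives were not run. In simulated footprint counts with 2 libraries per genotype and few changed genes, the recovery of 2-fold changes was 2%.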

Other observations

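The tests on zeros within a genotype and on absent mRNA were chosen only after the result was seen. Amino acid transporters outside the list of glutamine transport and metabolism had 8 falls and 1 rise among 18 in translational efficiency, or 11 and 1 adjusted over the list alone, without passing camera (adjusted p = 0.165), although fry called the list lower (0.000383), as it did in footprints (0.0156, camera 0.121). The proton-coupled transporter SLC36A1 (−1.07), SLC38A10 (−1.26) and SLC3A2 (−0.83), the heavy chain of several exchangers, fell, and the glutamate transporter SLC1A3 rose (3.90 ± 0.56 SE). The SLC3A2 call was lost without RNA WT 2 (adjusted p = 0.0613), RNA KO 2 (0.0516) or footprint WT 1 (0.0553). The cap-binding factor EIF4E fell in translational efficiency (−2.02 ± 0.34), 1 of 41 translation factors to fall with 3 that rose, or 1 fall and no rise adjusted over the list alone (camera adjusted p = 0.165). Cholesterol synthesis genes had 4 falls and 2 rises of 23, the same adjusted over the list alone (camera adjusted p = 0.371, fry 0.0111). Targets of the stress factor ATF4 had 7 rises and 5 falls of 29 in RNA, or 9 and 5 adjusted over the list alone, among them the cystine transporter SLC7A11 (1.51) and DDIT3 (1.26) (camera adjusted p = 0.443).

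Genes of tRNA modification went both ways in RNA, with 12 rises and 11 falls of 51, or 13 and 12 adjusted over the list alone (camera adjusted p = 0.855). Among them the methyltransferase TRMT13 rose (1.18 ± 0.19 SE), and ELP3, the catalytic subunit of the elongator complex, fell in RNA (−0.58) and rose in translational efficiency (1.41). Epithelial junction genes had 4 falls and 1 rise of 12 in RNA, or 4 and 2 adjusted over the list alone, with CDH1 at −1.01, KRT8 at −0.68 and KRT18 at −0.62 (camera adjusted p = 0.553, fry 0.0034). The median of that list was 0.179, and 7 of its 12 members had a positive change, so the falls were not shared by the list. Mesenchymal genes had 3 rises and 4 falls of 13, or 4 and 5 adjusted over the list alone, with the fibronectin FN1 at 0.64 and the cadherin CDH2 at −0.74 (camera adjusted p = 0.855). In footprints, AFP, the fetal form of albumin, fell (−1.85 ± 0.25) and albumin ALB rose (1.80 ± 0.17), and AFP lost its call with library totals (adjusted p = 0.0539) and without any 1 footprint library.

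In footprints, 37 genes had no count in both WT libraries and at least 50 in both KO libraries, and 16 had the reverse, while no gene did so in RNA. Absent mRNA is excluded for the set, since 30 of the 53 genes had more than 3 counts in every RNA library of the genotype at 0. Overlap with another gene was not more frequent in the set. It was found in 44.4% of the 45 genes with a position and in 58.1% of the other genes tested. The ratio was 0.765 (Fisher's exact p = 0.0701, two-sided). Whole gene spans were compared, and with overlap this common the 2-fold excess set as the mark of shared reads was out of reach. Reads shared with an overlapping gene therefore stay open, and ISY1-RAB43 and MROH7-TTC4 do share reads with partners. Counting or gene assignment in single libraries stays open: at least 51 genes were at 0 in 1 library and at 50 or more in the other library of the same genotype. In addition, 33 genes were at 0 in both libraries numbered 1 and at 50 or more in both numbered 2, and 4 had the reverse. The crossed splits, WT 1 with KO 2 and WT 2 with KO 1 at 0, held 9 and 5 genes. Such an effect may account for part of the set.

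Differences between RNA replicates followed the KO and WT axis: WT 3 over WT 2 had a Spearman rho of −0.194 across genes with KO 1 over WT 1, and KO 3 over KO 2 had 0.256. A library effect related to gene length may account for this as a hypothesis, since rho with genomic length was −0.244 for WT 3 over WT 2 and 0.295 for KO 3 over KO 2, across 14135 genes that are not independent replicates. Without both libraries numbered 3, 95.4% of the 5069 genes called in RNA kept their sign at an unadjusted p under 0.05 by edgeR. That bar is looser than a call, and the remaining libraries had also served to pick these genes. At the call threshold 3881 of the 5069 were still called. Most calls thus did not rest on the libraries numbered 3 alone, while a dependence of the others on them stays open. Differences between the cultures of a genotype were not tested.

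Of 10 splits of the 6 RNA libraries, too few for a share under 0.05, the real split called 5069 genes and the highest other 1, and for gene lists 7 and 4. Of 60 splits within assays for translational efficiency, 3 called at least 2291 genes, the real split among them. Chance is therefore not excluded for that count (2291 genes, highest other 6103). The split with 6103 keeps the RNA libraries as labelled and exchanges the genotypes of the footprint libraries. The third, with 2704, keeps the footprint libraries as labelled and sets RNA WT 1, KO 2 and KO 3 against the other RNA libraries. Both join KO RNA with WT footprints in whole or in part, which points to a structure of the samples, the shared RNA and footprint difference between genotypes. Neither is thus free of the genotype difference, so the share of splits cannot decide on chance for the gene count. For gene lists in translational efficiency, the highest other split of the 60 called 9 lists, and 4 splits reached that. Only the real split called 10 lists, a share under 0.05 but by a margin of 1 list, and for these libraries alone, which may be technical. That count was 6 without footprint WT 2 and 0 with an estimated correlation.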
